A study of Mus musculus with 15 samples.

How the data were processed

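RNA was measured in 15 sequencing libraries of myeloid cells sorted by flow cytometry from mouse hindbrain, which per the labels is brainstem with cerebellum. The series text also names a droplet platform and animals given donor cells, which the sample labels do not, and the labels were followed. The sort took cells carrying CD45 and CD11b, surface proteins found on microglia and on other myeloid cells. Animals were wild type (WT) or Twitcher (Twi), a mutant of Galc used as a model of Krabbe disease, at postnatal day 10, 15 or 20 (P10, P15, P20). Groups held 2 libraries (WT at P10 and P15, Twi at P15) or 3 libraries (WT at P20, Twi at P10 and P20). The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries. Per the labels, libraries were made with a low-input kit with 16 to 19 PCR cycles and sequenced in batch 1 (4 libraries) or batch 2 (11 libraries), at 29 to 42 M read pairs with a mean of 70.24% mapped. Batch 1 held a WT library at each age but a Twi library only at P10. Batch is thus partly confounded with genotype at P15 and P20. Amplified reads without molecular identifiers are not independent molecules.

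Per the submitters' processing notes, reads were quantified with kallisto 0.46.0 and the build named is GRCm39. The authors deposited a table of TMM-normalized log2 CPM and a table of TPM, each with 29957 rows and the same libraries; 1 row has no gene name and held 0.0282% to 0.0687% of each library. The lowest value of the deposited log2 table was -3.44, and 8845 named rows never rose above it. The deposited TPM values summed per library to 87.7% to 89.8% of the total that TPM has by definition. Low CPM values were tested for whole reads: 34.3% to 46.7% lay within 0.05 of a whole multiple of the smallest step, so whole reads could not be recovered and no count test was run. Depth per library in reads was therefore taken only from the labels. Gene symbols are those of the deposited tables, and no coordinates are printed because the annotation at hand is of another build.

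The column of a WT library at P10 carries a number that no label in its group has. This library was used as a replicate of that group without a number, and given batch 1, the batch left in its group; batch 2 was tried as well. Of the Xist and Y-linked genes meant as a sex covariate, Xist was not used here, so the covariate is the mean of Ddx3y, Kdm5d, Eif2s3y and Uty, which was high in 5 of the 15 libraries. These were WT P10 replicate 1, WT P20 replicates 1 and 3, Twi P10 replicate 2 and Twi P20 replicate 2. The groups at P10 and P20 were thus not balanced for it, while all P15 libraries were low.

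The 13292 genes with at least 1 CPM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3: 1 linear fit of 6 genotype-by-age groups plus batch on the log2 CPM values, with trended, robust empirical Bayes variance and 8 residual degrees of freedom before moderation. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Contrasts were Twi against WT at each age, the mean of those 3 contrasts, P20 against P10 within each genotype, and the genotype-by-age interaction as a moderated F test. Fold changes are on the deposited log2 CPM scale and understate changes of genes near its lowest value. Where all libraries of a group lay at that value, levels are given and no fold.

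Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured genes within a contrast; camera with an estimated correlation and fry were run beside it. The 18 function lists and 13 cell type lists, the groups, the tests, all alternatives but 1, and the rule for named genes were fixed before the data were examined. Oligodendrocyte precursors (2 measured genes) and choroid plexus with ependyma (4 measured genes) had too few genes to test. The rule names Galc first; then the 10 highest and 10 lowest fold changes among called genes whose groups do not overlap (for the mean over ages, with the same sign at all 3 ages), leaving out predicted and unnamed genes; the 5 smallest p where fewer than 5 passed in a direction; up to 4 members with the smallest p in each described list; and the 10 smallest p of the interaction test. Names were taken in that order and some were left out for length.

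Simulated data with 300 genes changed at each size, summed over 3 simulations, gave the share recovered. Changed genes were drawn from the more abundant ones, and Twi changes were the same at every age. Noise was normal and independent between genes, without a lowest value. The shares therefore do not cover genes near the table's lowest value or correlation between genes. For Twi against WT at P20, 44.3% of changes of 1 log2 unit and 84.7% of changes of 2 log2 units were called; at P15 28.0% and 76.7%; at P10 39.0% and 82.7%. For the mean over ages the shares were 78.7% and 95.3%, for WT P20 against P10 38.3% and 83.3%, and for Twi P20 against P10 47.7% and 87.3%. False calls made up 3.38% to 5.93% of calls.

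Alternatives were no batch term, batch 2 libraries alone, the replicate number as a block, no filter on low genes, a minimum of 5 CPM, log2(TPM + 1), log2(TPM + 0.1), a shift of each library to a common median, quantile normalization, non-robust variance, library quality weights, fits of the compared groups alone, a minimum fold change of 2, the Y-linked covariate, and each library left out in turn. Where a group was left with 1 library, it was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9.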

Results

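The series measured gene expression in CD45- and CD11b-positive cells of the hindbrain of Twi and WT mice at P10, P15 and P20. Twitcher mice lack working galactosylceramidase, the lysosomal enzyme encoded by Galc that breaks down galactosylceramide and psychosine. Each library had 15708 to 16870 genes above the lowest value of the table. The 10 most abundant genes took 10.6% to 12.9% of each library. Within groups, libraries correlated at r = 0.935 to 0.961 across genes, which are not independent replicates.

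Galc itself was lower in every Twi library than in every WT library. It measured 62.2 ± 8.88 CPM (SD, n = 2) in WT and 4.50 ± 0.666 CPM (SD, n = 3) in Twi at P10. At P15 the levels were 29.8 ± 2.51 CPM (SD, n = 2) and 6.29 ± 1.14 CPM (SD, n = 2), and at P20 36.2 ± 0.883 CPM (SD, n = 3) and 6.87 ± 1.85 CPM (SD, n = 3). The Galc log2 fold change was -3.77 ± 0.27 (SE) at P10, -2.24 ± 0.31 at P15 and -2.42 ± 0.25 at P20, with limma adjusted p of 2.1e-05, 0.0127 and 0.00027.

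**Figure D1:**
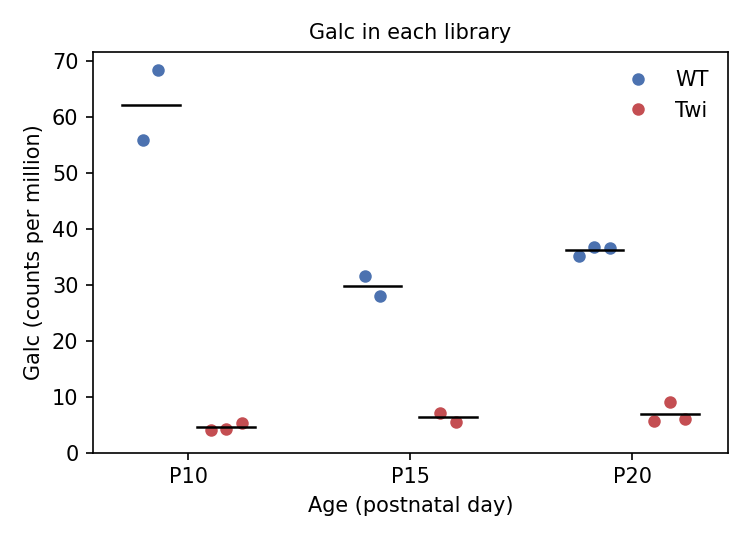
Galc in CPM (vertical axis) by age in days (horizontal axis), with a point per library and a line at each group mean, WT in blue and Twi in red. The highest Twi library, at 9.0 CPM, lies below the lowest WT library, at 28 CPM.

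At P20, the comparison asks how the mutation changes these cells at the latest age sampled. By camera, lists of interferon-stimulated, inflammatory cytokine and NF-kB, MHC class I and cell cycle genes were higher in Twi, and the list of homeostatic microglia genes was lower. The cytokine and MHC class I calls held with an estimated correlation, and the others did not (adjusted p = 0.0718 for interferon, 0.108 for cell cycle and 0.135 for homeostatic genes). Among the strongest rises were Il12b, a subunit of interleukins (log2 fold change 7.27 ± 0.87 SE), and the chemokines Cxcl13 (6.41 ± 1.19) and Cxcl10 (4.63 ± 0.58). Others were Irg1, which makes itaconate (6.21 ± 1.05), Nlrc5, an activator of MHC class I genes (5.30 ± 0.80), and Mmp12, a macrophage metalloproteinase (5.10 ± 0.53). Mmp12 went from 9.42 ± 3.55 CPM (SD, n = 3) in WT to 309 ± 22.2 CPM (SD, n = 3) in Twi, while Il12b went from 0.263 ± 0.194 to 34.4 ± 9.53 CPM. Ociad2 (5.0 ± 0.55) and Fam83d (4.73 ± 0.93) rose at low levels of about 3.02 and 2.18 CPM in Twi. Ttyh3 and Tnfrsf4, at the table's lowest value in all 3 WT libraries, reached 4.62 ± 2.16 and 2.70 ± 1.38 CPM (SD, n = 3) in Twi. The largest falls besides Galc were in Rgl3 (-5.18 ± 0.98), Pomgnt2 (-4.52 ± 0.77), the glutamate receptor Grm3 (-3.78 ± 0.60), Sipa1l1 (-3.72 ± 0.48) and Zfp551 (-2.78 ± 0.41), of which Sipa1l1 was the most abundant in WT at 20.8 CPM. Cxcl12 was at the table's lowest value in all 3 Twi libraries and at 0.661 ± 0.420 CPM in WT.

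Of the interferon list at P20, 29 of 38 measured genes were called higher and 37 adjusted over the list alone, with a median log2 fold change of 1.86. Oas1a, of the oligoadenylate synthetases that sense double-stranded RNA (2.57 ± 0.29), its relative Oasl2 (2.57 ± 0.32) and Ifi204 (2.18 ± 0.26) were among them. Reads of such close paralogs can be shared. The list passed camera (adjusted p = 5.82e-40), with adjusted p = 0.0718 with an estimated correlation. Inflammatory cytokine and NF-kB genes had 14 of 31 called higher (20 adjusted over the list alone, median 1.56), including Ccl7 (3.62 ± 0.29), Ccl2 (3.55 ± 0.28) and Tlr2 (1.08 ± 0.13). MHC class I had 9 of 21 higher (14 adjusted over the list alone, median 0.71), with H2-Q6 at 3.5 ± 0.39, H2-K1 at 1.23 ± 0.18 and the peptide transporter Tap1 at 1.19 ± 0.19. H2-Q6 has near-identical relatives. These last lists held with an estimated correlation, at adjusted p = 0.0283 for cytokines and adjusted p = 0.0330 for MHC class I. MHC class II had 0 of 13 called (0 adjusted over the list alone, median 0.18) and did not pass camera (adjusted p = 0.319).

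Cell cycle genes at P20 had 16 of 36 called higher and 35 adjusted over the list alone, with a median of 1.32 and all 36 above 0. Mki67 rose by 1.55 ± 0.19, the cyclin Ccnb1 by 1.72 ± 0.30, the replication factor Mcm2 by 1.58 ± 0.27 and the kinase Aurka by 1.72 ± 0.31. The camera call (adjusted p = 2.03e-26) was not kept with an estimated correlation (adjusted p = 0.108). Homeostatic microglia genes had 6 of 25 called lower (15 adjusted over the list alone, median -0.56), among them the purinergic receptor P2ry12 (-1.09 ± 0.18), Slc2a5 (-1.10 ± 0.19), Gpr34 (-0.85 ± 0.16) and Selplg (-0.85 ± 0.19). That list had adjusted p = 0.135 with an estimated correlation. Disease-associated microglia genes had 8 of 29 higher (12 adjusted over the list alone, median 0.83), led by Axl (1.45 ± 0.23), Cst7 (1.60 ± 0.28), Csf1 (1.42 ± 0.25) and Ch25h (3.85 ± 0.69), with adjusted p = 0.317 with an estimated correlation. Complement and phagocytosis genes went both ways, 4 higher and 2 lower of 31 (9 and 3 adjusted over the list alone), with Cfb at 2.85 ± 0.19. The adjusted p was 0.235 with an estimated correlation. Of the lysosome list, 3 genes were higher and Galc was lower among 48 (8 and 2 adjusted over the list alone). The rises were Ctsz (0.56 ± 0.14), Ctsb (0.52 ± 0.13) and Gla (3.22 ± 0.80), an alpha-galactosidase. The adjusted p was 0.410 with an estimated correlation. Of 34 sphingolipid genes, Gla and Galc were the called ones (2 higher and 2 lower adjusted over the list alone), and the list did not pass camera (adjusted p = 0.942).

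The lists that follow had at most 3 called genes each at P20, and all but the last passed camera. Stress response genes had 3 of 24 higher (5 adjusted over the list alone). These were the serine synthesis enzymes Psat1 (1.36 ± 0.22) and Phgdh (0.66 ± 0.12) and the cystine transporter Slc7a11 (1.23 ± 0.24), with adjusted p = 0.235 with an estimated correlation. Lipid uptake and storage genes had Ch25h higher and Lpcat3 lower (-0.63 ± 0.16) among 32 (3 and 1 adjusted over the list alone; adjusted p = 0.358 with an estimated correlation). Cholesterol synthesis had 0 of 24 called (0 adjusted over the list alone; median 0.28; adjusted p = 0.358 with an estimated correlation). Early genes induced by dissociation had 2 of 24 higher (5 higher and 2 lower adjusted over the list alone), Ccl3 (1.63 ± 0.32) and Socs3 (1.86 ± 0.38), with adjusted p = 0.408 with an estimated correlation. Ribosomal protein genes had 0 of 52 called (0 adjusted over the list alone) with a median of 0.72, oxidative phosphorylation 0 of 37 (0 adjusted over the list alone) with 0.27, and mitochondrially encoded genes 1 of 13, mt-Co1 (7 adjusted over the list alone), with 0.46. These had adjusted p = 0.408, 0.514 and 0.318 with an estimated correlation. Glycolysis and hypoxia genes had 0 of 22 called (0 adjusted over the list alone) and did not pass camera (adjusted p = 0.378).

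Among markers of other cells at P20, monocyte markers had 1 of 19 called, the chemokine receptor Ccr2 (1.56 ± 0.38), with 3 adjusted over the list alone, a median of 0.85 and adjusted p = 0.358 with an estimated correlation. Neutrophil markers had 0 of 18 called and a median of 0.27, and neuronal markers 0 of 13 and a median of 0.72, with 0 adjusted over the list alone in each. Neither list passed camera, at adjusted p = 0.361 and 0.0712. Border-associated macrophage markers had 1 of 19 called, Maf (-0.48 ± 0.12), with 1 adjusted over the list alone, a median of 0.59 and no camera call (adjusted p = 0.243). No gene was called among markers of T and NK cells (13 measured), B cells (8), dendritic cells (13), oligodendrocytes (14), astrocytes (12), endothelial and mural cells (8) or erythroid cells (9), and none of these lists passed camera. Adjusted over the list alone, 3 dendritic cell markers and 1 astrocyte marker were higher, and 1 endothelial or mural marker was higher and 1 lower. Dendritic cell markers had a median of 0.35 (camera adjusted p = 0.125) but a mean of 0.94 ± 0.19 (SE), with Ccr7 at 3.74 ± 1.01, Clec9a at 3.08 ± 0.96 and Ccl22 at 2.36 ± 0.78. The mean of monocyte markers was 0.91 ± 0.35.

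**Figure D2:**
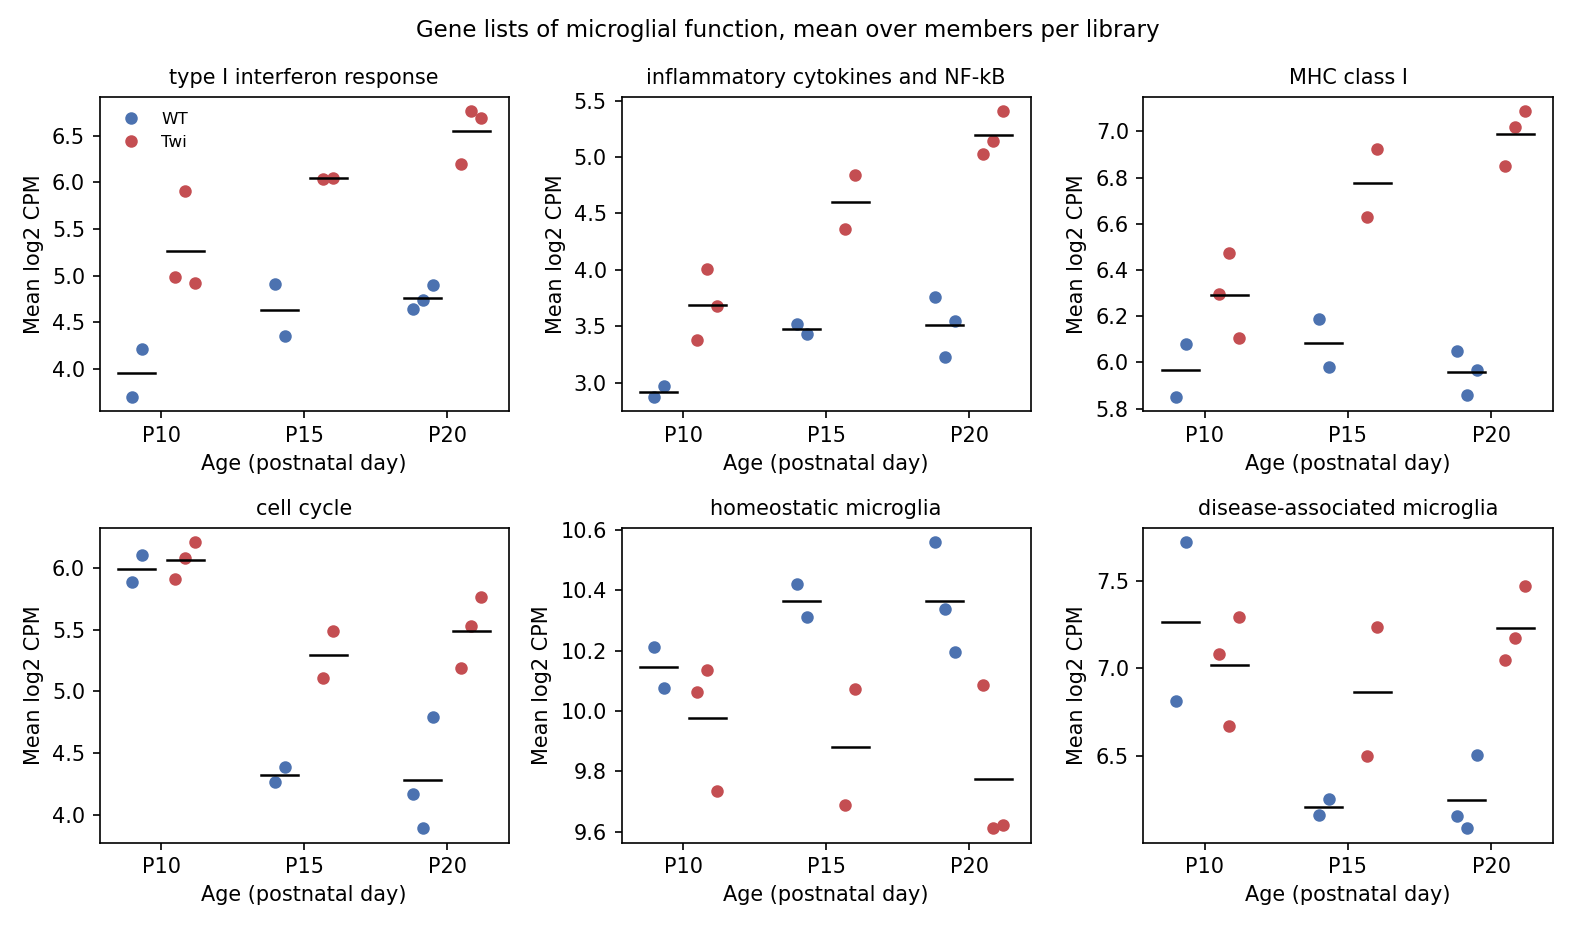
Mean log2 CPM over the members of 6 gene lists (vertical axes, each with its own range) by age in days, with a point per library and a line at each group mean, WT in blue and Twi in red. Every Twi library at P20 lies above every WT library at P20 for the interferon, cytokine, MHC class I, cell cycle and disease-associated lists and below for the homeostatic list.

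In all, 465 of 13292 genes were called at P20, 322 higher and 143 lower, and 462 of them had groups that do not overlap, against 22% of all genes and 10% by chance for 3 libraries against 3. Shifting libraries to a common median gave 266 higher and 184 lower. Library quality weights gave 556 higher and 375 lower, and a fit of the P20 libraries alone gave 92 higher and 10 lower. The count was 217 without WT replicate 1, 168 without WT replicate 2, 186 without Twi replicate 2 and 229 without Twi replicate 3, and 141 in batch 2 libraries alone, where 124 were higher and 17 lower.

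At P15, Twi cells again had higher Il12b, whose WT libraries were both at the table's lowest value and whose Twi level was 17.5 ± 12.8 CPM (SD, n = 2). Gpnmb, a lysosomal stress glycoprotein (5.85 ± 0.93), Ch25h, which makes 25-hydroxycholesterol (5.53 ± 0.86), the heparanase Hpse (4.83 ± 0.67), Mmp12 (4.12 ± 0.67), Cd69 (3.33 ± 0.61), H2-Q6 (3.08 ± 0.48), Oas2 (3.08 ± 0.57), Plk2 (3.02 ± 0.43) and the replication factor Mcm10 (2.77 ± 0.44) also rose. Galc and Tuft1, which was at the table's lowest value in both Twi libraries, were the genes called lower. Values that did not pass were Cldn12 (-3.90 ± 0.76), Susd3 (-0.95 ± 0.19) and Rtn1 (-1.92 ± 0.40).

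The interferon list at P15 had 5 of 38 genes called higher and 31 adjusted over the list alone, with a median of 1.29, Herc6 (1.2 ± 0.18) and Oas1a (2.42 ± 0.37) among them. Its adjusted p = 0.107 with an estimated correlation. Cytokine genes had 3 of 31 higher (7 higher and 1 lower adjusted over the list alone), Il12b, Ccl2 (2.24 ± 0.35) and Ccl7 (2.14 ± 0.36), and MHC class I had H2-Q6 and H2-K1 (1.27 ± 0.22) among 21 (6 adjusted over the list alone), each with adjusted p = 0.107 with an estimated correlation. Cell cycle genes had 2 of 36 called, Mki67 (1.86 ± 0.24) and Mcm3 (1.05 ± 0.17), and 18 adjusted over the list alone, with a median of 1.03 and adjusted p = 0.181 with an estimated correlation. Homeostatic genes had a median of -0.45 with 0 of 25 called (0 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation), the lowest p being for Cst3 (-0.87 ± 0.27). Disease-associated genes had 2 of 29 higher, Gpnmb and Ch25h (6 adjusted over the list alone; adjusted p = 0.582 with an estimated correlation). Pltp, a phospholipid transfer protein, rose by 2.48 ± 0.44 and Cfb by 1.92 ± 0.23. Monocyte markers had a median of 0.64 and border-associated macrophage markers of 0.96, each with 0 of 19 called and adjusted p = 0.582 with an estimated correlation, and neutrophil markers a median of -0.011 and no camera call (adjusted p = 0.779). Lysosomal genes (median 0.12), glycolysis and hypoxia genes (0.21), mitochondrially encoded genes (0.21) and erythroid markers (-1.38) also passed camera. With an estimated correlation their adjusted p was 0.582, 0.582, 0.692 and 0.582. The direction of the mitochondrially encoded genes was not stable, with a median of -0.065 without Twi P15 replicate 2.

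At P15, 36 genes were called, 34 higher and 2 lower, and 1375 had an unadjusted p under 0.05. All 36 had groups that do not overlap, as did 39.2% of all genes. Smaller groups separate more often by chance, so such shares cannot be compared between contrasts with different group sizes. The count was 11 without WT P15 replicate 1, 19 without Twi P15 replicate 1 (10 higher and 9 lower), 45 without Twi P15 replicate 2 (18 higher and 27 lower), 77 without WT P20 replicate 3 and 0 in a fit of the P15 libraries alone. Twi P15 replicate 1 stood apart on the third principal component, at 79.3 against 22.1 for the next highest library.

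At P10, the same comparison gave a short set of genes. Mmp12 (4.12 ± 0.58), Cxcl10 (3.93 ± 0.63), the activation marker Cd69 (3.69 ± 0.53), Madcam1 (3.66 ± 0.58), Arhgef37 (3.0 ± 0.44), the coagulation factor F5 (2.60 ± 0.37), Ifit1 (2.40 ± 0.38) and complement factor Cfb (1.22 ± 0.20) were higher in Twi. Ttyh3 was at the table's lowest value in both WT libraries and at 6.38 ± 1.78 CPM (SD, n = 3) in Twi. Galc and Ap3m2, the latter at the lowest value in all 3 Twi libraries and at 2.85 CPM in WT, were lower. Sepp1 (-0.80 ± 0.15), the cathepsin Ctsa (-0.50 ± 0.12) and Abca9 (-0.52 ± 0.13) did not pass.

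All 38 interferon genes had positive fold changes at P10, with 2 called and 30 adjusted over the list alone, a median of 1.33 and adjusted p = 0.0784 with an estimated correlation. Cytokine genes had 0 of 31 called (7 adjusted over the list alone; median 0.69; adjusted p = 0.0784 with an estimated correlation), with Il1b at 1.32 ± 0.36 and Ccl2 at 1.11 ± 0.31. Markers of other cells differed as well: neutrophil markers had a median of 1.41 (0 of 18 called, 9 adjusted over the list alone), monocyte markers 1.04 (0 of 19, 7 adjusted over the list alone) and neuronal markers -1.22 (0 of 13, 0 adjusted over the list alone). Their adjusted p with an estimated correlation was 0.0784, 0.147 and 0.0784. Cell cycle genes had a median of 0.05 and did not pass camera (adjusted p = 0.497). Lysosomal genes had a median of -0.18 with Galc alone called among 48 (3 lower adjusted over the list alone; adjusted p = 0.147 with an estimated correlation). MHC class I (median 0.31), erythroid markers (1.85), oligodendrocyte markers (-0.19), disease-associated genes (-0.25) and lipid uptake and storage genes (-0.11) also passed camera. With an estimated correlation their adjusted p was 0.253, 0.413, 0.475, 0.526 and 0.491. The direction was not stable for some of them. Disease-associated genes had a median of 0.19 and lipid genes of 0.065 in batch 2 libraries alone. Disease-associated genes had 0.16 without the unnumbered WT P10 library and 0.048 with the replicate block, and oligodendrocyte markers 0.0072 without WT P10 replicate 1.

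At P10, 11 genes were called, 9 higher and 2 lower, all with groups that do not overlap (21.2% of all genes), and 737 genes had an unadjusted p under 0.05. The count was 1 without WT P10 replicate 1, Twi P10 replicate 1 or Twi P20 replicate 2, each time a lower gene, 3 without the unnumbered WT P10 library or Twi P10 replicate 2, 2 without Twi P10 replicate 3, 6 without Twi P20 replicate 3, 7 without either Twi P15 library and 17 without Twi P20 replicate 1. With log2(TPM + 1) it was 0 higher and 2 lower, and with no filter on low genes 9 higher and 17 lower.

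Averaged over the 3 ages, Il12b, Ttyh3 and Cxcl13 were higher in Twi, with a WT group at the table's lowest value and so no fold. Mmp12 (4.45 ± 0.36), Cd69 (3.87 ± 0.33), Irg1 (3.71 ± 0.71), Cxcl10 (3.54 ± 0.39), Madcam1 (3.54 ± 0.36), Nlrc5 (3.28 ± 0.54) and the chemokine receptor Ccr7 (3.28 ± 0.68) were also among the highest. Apba2, Fn3k and Cxcl12 were lower, with a Twi group at that lowest value. Pomgnt2 (-2.18 ± 0.52), Sipa1l1 (-1.86 ± 0.32), Rnase10 (-1.60 ± 0.25), Zfp36l1 (-1.39 ± 0.19) and Rtn1 (-1.22 ± 0.22) were among the lowest besides Galc (-2.81 ± 0.17). Of the interferon list 34 of 38 were called higher (38 adjusted over the list alone, median 1.65), of MHC class I 8 of 21 (13 adjusted over the list alone, median 0.40) and of the cytokine list 14 higher and 1 lower of 31 (20 and 2 adjusted over the list alone, median 0.87). With an estimated correlation their adjusted p was 0.0291, 0.0287 and 0.0209. Cell cycle genes had 12 of 36 higher (34 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation), homeostatic genes 3 of 25 lower (15 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation) and monocyte markers 3 of 19 higher (16 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation). The other lists that passed camera were neutrophils (median 0.59), border-associated macrophages (0.56), disease-associated microglia (0.21), complement and phagocytosis (0.078), stress response (0.12), dissociation-induced early genes (0.40), ribosomal proteins (0.21) and mitochondrially encoded genes (0.22). None of these held, at adjusted p = 0.398, 0.672, 0.505, 0.311, 0.337, 0.439, 0.672 and 0.505 with an estimated correlation, and the ribosomal median was -0.053 without WT P10 replicate 1. The mean of dendritic cell markers was 0.57 ± 0.13 (SE), without a camera call (adjusted p = 0.141). In all 388 genes were called, 301 higher and 87 lower. A common median gave 265 and 128, and log2(TPM + 0.1) gave 278 and 36. Of the 388 genes, 344 had the same sign at all 3 ages, as did 34.2% of all genes. The count was 101 without WT P10 replicate 1, 153 without WT P15 replicate 1, 252 without WT P20 replicate 2, 206 without Twi P10 replicate 2 and 141 in batch 2 libraries alone.

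Whether the Twi effect differed between ages was tested with the interaction F test, which called 0 genes with limma, with 1043 genes at an unadjusted p under 0.05. It called 1 gene without WT P20 replicate 2, 5 without Twi P15 replicate 1 and 6 without Twi P15 replicate 2. The smallest p values were for Ociad2, Ccl7, Bbs9, Ap3m2, Tacc3, Ctsb, Rad51ap1, Fen1, Ch25h and Mki67, none of which passed. The P20 effect minus the P10 effect alone called Ccl7, with a difference of 3.15 ± 0.42 and limma adjusted p = 0.0435. Effects at different ages fell partly on shared genes in the joint fit. Of the 34 genes higher at P15, 31 were also called higher at P20, against 0.824 for independent lists. Of the 9 genes higher at P10, 7 were, against 0.218. That fit shares each gene's variance and the batch term between ages, so the lists are not independent. Fits of each age alone called 0 genes at P15 and 1 at P10, too few to repeat the overlap. Across genes, which are not independent, effects at P15 and P20 correlated at Pearson's r = 0.359 (Spearman's rho = 0.326), at P10 and P20 at r = 0.148 (rho = 0.128) and at P10 and P15 at r = 0.104 (rho = 0.0868). In fits of each age alone, which share no batch term, r was 0.243, 0.109 and 0.0672.

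In WT cells, P20 against P10 shows the difference between ages in these sorted libraries. Markers of neutrophils and neurons differed too, so changes within cells and in the mix of cells caught are not separated. Cell cycle genes fell, with 31 of 36 called lower (34 adjusted over the list alone, median -1.82), including Mcm3 (-1.33 ± 0.15), Mki67 (-1.84 ± 0.21) and Ccnb1 (-2.69 ± 0.32), though adjusted p = 0.138 with an estimated correlation. The disease-associated genes Gpnmb (-6.76 ± 0.81), Igf1 (-3.29 ± 0.41), Gpx3 (-3.97 ± 0.52) and Ctsb (-1.48 ± 0.14) fell, as did Mcoln3 and Mfap4, which went from 10.4 and 12.8 CPM to the table's lowest value in all 3 P20 libraries. Rises included Klrd1 (4.14 ± 0.62), Fut7 (3.99 ± 0.77), Mctp2 (3.93 ± 0.69), Mefv (3.71 ± 0.78), Ptgir (3.65 ± 0.70), Hbb-bt (5.11 ± 1.28), Igkc (3.64 ± 0.96) and the neutrophil gene Retnlg (3.58 ± 0.59).

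Disease-associated genes had 10 lower and 2 higher of 29 (15 and 2 adjusted over the list alone), lysosomal genes 13 lower and 1 higher of 48 (18 and 3 adjusted over the list alone) with Hexa at -1.14 ± 0.17 and Gusb at -1.28 ± 0.19, and lipid uptake and storage genes 10 lower and 1 higher of 32 (12 and 3 adjusted over the list alone) with the sterol transporters Abcg1 (-1.70 ± 0.21) and Abca1 (-1.34 ± 0.17). Their adjusted p was 0.414, 0.202 and 0.301 with an estimated correlation. Neutrophil markers had all 18 called higher (18 adjusted over the list alone, median 2.63), such as Mmp9 (2.61 ± 0.38) and Lcn2 (2.97 ± 0.47), and monocyte markers 9 of 19 (14 adjusted over the list alone, median 1.47), such as Chil3 (2.56 ± 0.34). Neuronal markers had 9 of 13 lower (10 adjusted over the list alone, median -3.44), such as Gap43 (-6.31 ± 0.77) and Stmn2 (-4.74 ± 0.72), and border-associated macrophage markers 8 of 19 (9 adjusted over the list alone, median -1.71), such as Folr2 (-4.41 ± 0.55) and Mrc1 (-2.81 ± 0.49). With an estimated correlation the adjusted p of these marker lists was 0.138, 0.262, 0.138 and 0.301. Homeostatic genes had 3 higher and 1 lower of 25 (6 and 2 adjusted over the list alone), with Selplg at 1.21 ± 0.21 and adjusted p = 0.491 with an estimated correlation. Interferon genes had 5 of 38 higher (13 adjusted over the list alone, median 0.69) and cytokine genes 8 higher and 1 lower of 31 (10 and 1 adjusted over the list alone, median 0.50). Mitochondrially encoded genes had 5 of 13 lower (10 adjusted over the list alone, median -0.65). With an estimated correlation their adjusted p was 0.345, 0.202 and 0.301. The other lists that passed camera were oligodendrocytes (median -1.12), dendritic cells (0.91), T and NK cells (0.59), erythroid cells (1.30), MHC class II (0.63), dissociation-induced early genes (0.37), oxidative phosphorylation (-0.37) and ribosomal proteins (-0.24). None of the lists held: for these, in order, adjusted p was 0.345, 0.188, 0.447, 0.414, 0.345, 0.301, 0.431 and 0.670 with an estimated correlation. The direction of ribosomal proteins was not stable, with a median of 0.38 in batch 2 libraries alone.

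**Figure D3:**
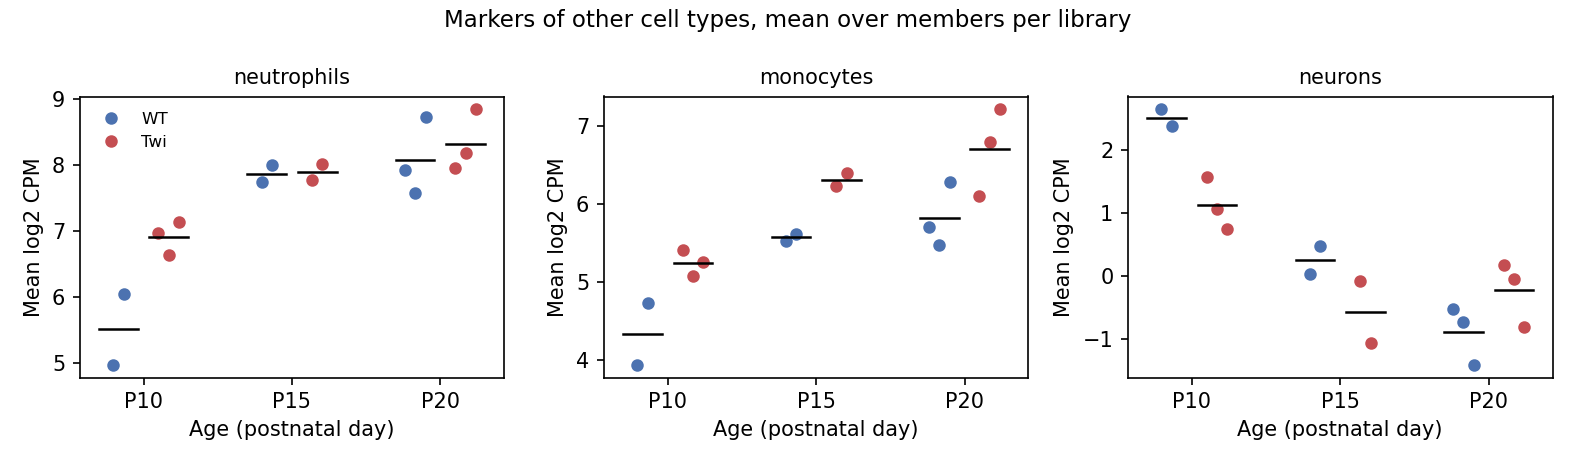
Mean log2 CPM over markers of neutrophils, monocytes and neurons (vertical axes, each with its own range) by age in days, with a point per library and a line at each group mean, WT in blue and Twi in red. Both WT libraries at P10 lie below the other libraries for neutrophil and monocyte markers and above them for neuronal markers.

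In WT, 1375 genes were called between P20 and P10, 625 higher and 750 lower, and 1372 had groups that do not overlap (42.3% of all genes). Between P15 and P10, 862 were called, and 0 between P20 and P15 with limma, where 398 had an unadjusted p under 0.05. The P20 against P10 count was 309 without WT P10 replicate 1, 446 without the unnumbered WT P10 library (236 higher and 210 lower), 734 without WT P20 replicate 1 and 198 in batch 2 libraries alone (110 higher and 88 lower).

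In Twi cells, the lists of cytokine and interferon genes were higher at P20 than at P10 by camera, and neuronal markers lower. The cytokine call held with an estimated correlation, and the others did not (adjusted p = 0.112 for interferon and 0.196 for neuronal markers). Il12b (6.75 ± 0.87), Ch25h (4.81 ± 0.69), Vcan (4.52 ± 0.99), Ccr7 (4.46 ± 1.01), the chemokine Ccl22 (4.05 ± 0.78), Igfbp6 (3.72 ± 0.74), Hcar2 (3.48 ± 0.36), Cd69 (3.26 ± 0.49) and Gadd45b (3.25 ± 0.72) rose most. Ap3m2 went from the table's lowest value in all 3 P10 libraries to 2.92 ± 1.07 CPM (SD, n = 3). The neuronal genes Tubb3 (-4.80 ± 0.94), Crmp1 (-4.63 ± 0.82) and Sox11 (-4.33 ± 0.57) fell, as did Ptn (-3.74 ± 0.79), Lppr1 (-3.69 ± 0.78) and Gpm6a (-3.56 ± 0.65). Cytokine genes had 16 of 31 called higher (22 higher and 1 lower adjusted over the list alone, median 1.51), which held with an estimated correlation at adjusted p = 0.00901. Interferon genes had 17 of 38 higher (36 adjusted over the list alone, median 1.27), MHC class I 7 of 21 (9 higher and 1 lower adjusted over the list alone) and MHC class II 2 of 13 (6 adjusted over the list alone), at adjusted p = 0.112, 0.0954 and 0.180 with an estimated correlation. Cell cycle genes had Mcm3 alone called (-0.72 ± 0.14) of 36, 1 adjusted over the list alone, with a median of -0.59 and adjusted p = 0.249 with an estimated correlation. Neutrophil markers had a median of 1.42 with 0 of 18 called (17 adjusted over the list alone) and monocyte markers 1.47 with 5 of 19 (14 adjusted over the list alone), each with adjusted p = 0.124 with an estimated correlation. In all 318 genes were called, 204 higher and 114 lower, 316 with groups that do not overlap (21.2% of all genes), and a common median gave 189 and 172. Lists that also passed camera included dissociation-induced early genes (5 of 24 higher, 9 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation) and dendritic cell markers (2 of 13 higher, 4 adjusted over the list alone, adjusted p = 0.0851 with an estimated correlation). Border-associated macrophage markers had 3 of 19 lower (7 adjusted over the list alone) and neuronal markers 2 of 13 lower (5 adjusted over the list alone), at adjusted p = 0.249 and 0.196 with an estimated correlation. The other lists that passed were cholesterol synthesis (median 0.21), complement and phagocytosis (0.18), stress response (0.40), ribosomal proteins (0.34), T and NK cells (0.55), oligodendrocytes (-0.66) and homeostatic microglia (-0.19). None of these held: in the same order, adjusted p was 0.260, 0.196, 0.124, 0.753, 0.483, 0.485 and 0.416 with an estimated correlation. The count was 100 without Twi P10 replicate 1, 118 without Twi P10 replicate 3, 105 without Twi P20 replicate 2, 182 without Twi P20 replicate 3 and 161 in batch 2 libraries alone.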

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

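The tests of cell share, batch and left-out libraries below were chosen after the results were seen; the counts over other splits of the libraries were planned before them.

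The Twi effect differed between P20 and P10, by a test of the difference itself, for Ccl7 (3.15 on the log2 scale). By camera with the preset correlation the same difference passed for 16 lists, given as medians: homeostatic microglia -0.45, disease-associated microglia 0.93, lysosome 0.30, cholesterol synthesis 0.32, lipid uptake and storage 0.64, interferon response 0.56, MHC class I 0.46, inflammatory cytokines 0.59, complement and phagocytosis 0.18, cell cycle 1.16, oxidative phosphorylation 0.40, ribosomal proteins 0.64, mitochondrially encoded genes 0.51, neutrophils -1.09, neurons 1.96 and erythroid cells -1.28. With an estimated correlation 0 of the 16 lists passed, the lowest adjusted p being 0.139. These differences rest in part on the 2 WT P10 libraries. The P10 direction of the ribosomal, oxidative phosphorylation and mitochondrially encoded lists turned when a WT P10 library was left out.

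Of the 10 splits of the 6 P20 libraries into groups of 3, the real split called 465 genes and the highest of the others 0; for Twi P20 against P10 the real split called 318 and the highest other 0. In each case 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05. For the mean over ages, 1 of 100 splits within ages, the real one, reached 388 genes. That share is under 0.05, so chance alone is unlikely there. It is not excluded, because the 100 splits were drawn from a larger number of possible ones. The highest other split called 281 and kept the true labels at P15 and P20.

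Interferon genes were higher in Twi at P20 by camera, though not with an estimated correlation (adjusted p = 0.0718). A gene brought by added cells cannot rise by more than markers that those cells alone carry. The mean rise of the interferon list exceeded that of monocyte markers by 0.95 ± 0.38 (SE), that of neutrophil markers by 1.58 ± 0.48 and that of dendritic cell markers by 0.92 ± 0.36. A list mean may also hold markers that microglia carry, or markers near the table's lowest value, whose rises are understated. If the listed markers come mostly from those cells, the values argue against a larger share of neutrophils as the whole source. For monocytes, of which the marker Ccr2 was called higher, and for dendritic cells, the markers rose unevenly. There the difference cannot decide. A rise of 1.73 ± 0.18 in batch 2 libraries alone argues against batch as the whole source. Single markers, none of them called, stood above the interferon median of 1.86, namely Ccr7 (3.74 ± 1.01), Clec9a (3.08 ± 0.96), Ccl22 (2.36 ± 0.78) and Ccl17 (2.35 ± 1.13) of dendritic cells and Vcan (2.39 ± 0.99) of monocytes, so more cells of a subset that carries them stay open. Monocytes or dendritic cells that are themselves more interferon-stimulated in Twi stay open, as does the genotype, which may act on the microglia directly. These comparisons cover the interferon list at P20 alone. The cytokine and MHC class I lists were not set against markers of other cells or early genes induced by dissociation. At P10 the mean rise was 1.35 ± 0.33 (SE) for the interferon list and 1.42 ± 0.44 for neutrophil markers, so a larger share of neutrophils stays open there.

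Cell cycle genes were higher in Twi at P20 by camera, though not with an estimated correlation (adjusted p = 0.108), and in batch 2 libraries alone the rise was 1.15 ± 0.34 (SE), which argues against batch. On the log2 scale the rise exceeded that of neuronal markers by 0.50 ± 0.64, so dividing neuronal precursors low in these markers, which the CD45 and CD11b sort should remove, cannot be told apart from dividing myeloid cells. Because that left the question open, further tests were added: in mean CPM over the list the rise at P20 exceeded that of neuronal markers by 35 ± 10.4, and at P15 the log2 rise exceeded it by 1.74 ± 0.80. If neurons carry more of their own markers than of cell cycle genes, these values argue against RNA of neurons. In mean CPM at P20 the neuronal list itself changed by -0.19 ± 1.65 (SE) and the cell cycle list by 34.8 ± 9.35. The most abundant neuronal markers in Twi at P20 were Snap25 at 4.71 and Zic1 at 1.81 CPM, against 2.76 and 0.96 CPM in WT. The lists share 0 genes.

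In WT cells neutrophil markers were higher and neuronal markers lower at P20 than at P10 by camera, though not with an estimated correlation (adjusted p = 0.138 for each). The lists moved apart by 5.97 ± 0.81 (SE), but they were picked for these directions, so that value restates the pattern and is no separate test. A lower share of microglia that raised all other markers alike would not by itself give the fall of neuronal markers. Without either WT P10 library the lower rise of neutrophil markers was 1.92 ± 0.53, so 1 library alone is not the source. The most abundant markers at P10 were Ngp, at 2145 CPM then and 9474 CPM at P20, and Neurod1, at 47 and 0.73 CPM, of cells that the CD45 and CD11b sort keeps and should remove, in that order. A change in the neutrophils and in the neuronal RNA caught by the sort, or in the animals with age, stays open, and with 2 libraries at P10 a difference in sorting between days was not tested.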

How the results depend on the processing

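The alternatives were planned, except batch 2 for the unnumbered WT P10 library, chosen after seeing the data, which gave P10 10, P15 34, P20 398, mean over ages 446, WT 1264 and Twi 280 called genes. Comparisons are named in that order below: Twi against WT at P10, P15, P20 and averaged, then WT and Twi P20 against P10. In the planned fit they called 11, 36, 465, 388, 1375 and 318 genes. No named gene that was called turned to the opposite sign.

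Batch 2 libraries alone gave 6, 15, 141, 141, 198 and 161, and 165 of 321 called gene and comparison pairs among the named genes stayed called; these fits have fewer libraries. Fits of the compared groups alone gave 1, 0 and 102 at the 3 ages, 395 in WT and 179 in Twi, with fewer libraries. Quality weights gave 20 at P10, 931 at P20, 2170 in WT, 658 in Twi and 6 for the interaction. No filter gave 26 at P10, 301 at P20 and 3 for the interaction. log2(TPM + 1) gave 2 at P10 and 61 at P15; log2(TPM + 0.1) gave 62 at P15, 304 at P20, 2 for the interaction, and 278 higher against 36 lower for the mean. No batch term gave 55 at P15. The Y-linked covariate gave 9, 28, 362, 337, 1064 and 258, in the order above. A minimum fold of 2 gave 290 at P20, 175 averaged and 831 in WT, by construction. Except as stated, the cause was not tested.

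Replicate numbers were not taken to pair the samples. Deviations of same-numbered libraries correlated at 0.227 at P10, 0.0404 at P15 and 0.0523, -0.0174 and 0.138 at P20. Those of other pairs ran from -0.227 to 0.13. In a group of 2 libraries the deviations mirror each other, so these values do not exclude pairing. With the number as a replicate block, 0, 1, 124 and 140 genes were called for the Twi effects, on fewer residual degrees of freedom.

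Groups left with 1 library were assumed to vary like the others. Leaving out each library gave 1 to 17 genes at P10, 11 to 77 at P15, 168 to 559 at P20, 101 to 524 averaged, 309 to 1481 in WT, 100 to 398 in Twi and 0 to 6 for the interaction. Named pairs kept ran from 200 to 300.

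Lists passing camera numbered 11, 12, 16, 14, 20 and 18; with an estimated correlation 0, 0, 2, 3, 0 and 1; with fry 0, 3, 7, 8, 13 and 10. Leaving out each library gave 7 to 16, 8 to 16, 11 to 18, 8 to 18, 15 to 20 and 15 to 19. Correlations of effects in fits of each age alone were 0.0672 (P10 and P15), 0.109 (P10 and P20) and 0.243 (P15 and P20).

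Reversed list medians, cause not tested, were at P10 in batch 2 alone disease-associated microglia 0.19 and lipid uptake 0.065, and under the block disease-associated microglia 0.048. At P10 without WT P10 replicate 1 they were ribosomal proteins -0.53 and oligodendrocytes 0.0072, and without the unnumbered WT P10 library disease-associated microglia 0.16, oxidative phosphorylation 0.34 and mitochondrially encoded genes 0.21. With that library in batch 2, ribosomal proteins were -0.17. At P15 mitochondrially encoded genes were -0.065 without Twi P15 replicate 2, and under the block their median stayed positive at 0.048 while the direction by camera turned; without Twi P15 replicate 1 oxidative phosphorylation was 0.33 and ribosomal proteins 0.58. Ribosomal proteins averaged -0.053 without WT P10 replicate 1, and in WT were 0.38 in batch 2 alone and 0.32 without the unnumbered library. Over all libraries left out in turn, the other ends of the ranges were, at P10, disease-associated microglia -0.74, ribosomal proteins 0.65, mitochondrially encoded genes -0.35 and oligodendrocytes -0.85. At P15 they were oxidative phosphorylation -0.57, ribosomal proteins -0.72 and mitochondrially encoded genes 0.51. For ribosomal proteins they were 0.46 averaged and -0.88 in WT. Low input and many PCR cycles limit precision for genes of a few CPM.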

Other observations

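All tests in this part were chosen after the results were seen. Of 11 gene families defined by symbol, with members of the fixed lists left out, the interferon-inducible GTPases and the Pyhin genes, which include sensors of DNA, stood higher in Twi at P20. Among 16 GTPases 7 were called higher, with Gbp2 at 2.47 ± 0.27 (SE), Tgtp2 at 2.11 ± 0.36, Ifi47 at 1.94 ± 0.34, Gbp3 at 1.28 ± 0.19 and Irgm1 at 1.15 ± 0.23. Among 8 Pyhin genes 5 were called, with Ifi205 at 3.53 ± 0.46, Pydc4 at 2.68 ± 0.40 and Mnda at 2.32 ± 0.43, and reads can be shared within both families. Both passed camera over the 11 families, with adjusted p = 0.0570 with an estimated correlation.

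Zfp zinc finger genes, mostly transcription factors, had a median of -0.28 at P20 over 304 members, with 6 called lower and 0 higher. Among them were Zfp36l1 (-1.82 ± 0.28), which is an RNA-binding protein, Zfp658 (-0.99 ± 0.15) and Zfp652 (-0.77 ± 0.16). The family passed camera (adjusted p = 1.0e-08), with adjusted p = 0.0570 with an estimated correlation. Schlafen genes had Slfn9 (1.18 ± 0.19) and Slfn2 (1.12 ± 0.19) higher among 6, with Slfn10-ps at -0.76 ± 0.30, and did not pass camera (adjusted p = 0.0862). Of 13 minichromosome maintenance and Fanconi genes outside the fixed lists, Fancd2 (1.84 ± 0.36), Mcm10 (1.68 ± 0.35) and Mcm8 (1.84 ± 0.41) rose, but the family median was -0.11 and the family did not pass camera (adjusted p = 0.123). Proteasome subunits had a median of 0.29 with 1 of 37 called. They passed camera (adjusted p = 2.42e-06), but not with an estimated correlation (adjusted p = 0.382). Parp, Trim, histone, potassium channel and serpin genes did not pass camera at P20. Schlafen genes did pass at P10, P15 and averaged over ages (adjusted p = 0.00427, 0.0104 and 0.00191), as did minichromosome maintenance and Fanconi genes at P15 and averaged (0.00288 and 0.0177). These calls were lost with an estimated correlation, at adjusted p = 0.225, 0.164 and 0.102, and 0.164 and 0.197. Parp genes passed at P15 and averaged and Trim genes at P10, also lost, at adjusted p = 0.0948, 0.102 and 0.398. GTPases and Pyhin genes passed at P10, P15 and averaged too, Zfp genes at P15 and averaged, and proteasome subunits averaged. With an estimated correlation these were lost, the lowest adjusted p being 0.0558. In WT at P20 against P10, Zfp genes had 15 higher and 3 lower (median 0.34) and proteasome subunits 8 of 37 lower. Their adjusted p was 0.208 and 0.373 with an estimated correlation.

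A hypothesis is that genes which change with age in WT stay nearer their P10 level in Twi. It predicts that Twi effects run against the WT change with age when measured on other libraries. The P20 effect correlated with WT P15 minus P10 at r = -0.151 across genes, and the P15 effect with WT P20 minus P10 at r = -0.0711. The sum, -0.222, was as low in 2 of 100 label splits within P15 and P20, the real one included, and the lowest other was -0.313. Without cell cycle genes the sum was -0.210, as low in 2 of 100 splits, with -0.309 the lowest other, but that list is too small a part of all genes to show whether cell cycle genes carry the pattern. The values are consistent with the hypothesis, but the correlations are small, genes are not independent, and a further sorted cell type that changes with age may give them as well.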
